A study of Mus musculus with 8 samples.

How the data were processed

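Messenger RNA levels were measured by sequencing in liver tissue of 5-week-old mice, in 5 libraries from Stab1 knockout mice and 3 from wild-type mice. Groups and replicate numbers came from the sample labels. Per the labels' protocols, RNA was isolated with a NucleoSpin column kit, its quality was checked on a Bioanalyzer, and libraries were made by standard Illumina procedures at BGI. The aligner, the counting method, the genome build, the gene annotation and the strandedness of the libraries are not given in the sources used here.

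The authors deposited a single gene table with 19464 rows. Per the file headers, it holds for each library a count of uniquely mapped reads per gene, and the header of each count column also carries a total that equals the column's sum. The deposited table also gives, per the file headers, the percent of each gene's length covered by reads, and this coverage percent was used only to compare libraries and to look at named genes. The deposited RPKM values (reads scaled by gene length and library total) were recomputed from the counts, totals and gene lengths and equalled them within rounding, so they hold no further information and were not tested. The count columns were therefore the measurement analysed. A dash in the table was read as 0. Reads were summed for 113 gene identifiers that stand on 229 rows, which left 19348 genes, of which 17474 had at least 1 read.

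Library totals were 4.85 M (mega) reads in knockout library 1, between 8.94 and 10.5 M in the other knockout libraries and between 10.1 and 10.8 M in the wild-type libraries. The largest library held 2.23 times the reads of the smallest. A floor of 3 reads corresponds to 0.619 CPM (reads scaled to library size) in knockout library 1 and to between 0.278 and 0.336 CPM in the others. Floors and exact intervals cover counting error only. No labels say whether libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. No pair of libraries agreed within sampling noise.

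Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few reads were removed with filterByExpr at its default settings, library sizes were scaled by the trimmed mean of M values (TMM), and 12338 genes were tested with the quasi-likelihood F test for knockout against wild type with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p below 0.05. The biological coefficient of variation was 24.8%. Positive log2 fold changes mean higher levels in knockout liver. The standard error (SE) of a log2 fold change was its size divided by the square root of F. CPM values were computed with the TMM-scaled library sizes. For Stab1 an exact two-sided permutation test on mean log2 CPM, with a prior count of 2, was run over the 56 ways of dividing the libraries.

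A total of 45 gene lists (liver cell types, zonation, metabolic pathways, stress, sex, clock and tissues that could contaminate a liver sample) were written before the data were examined. Of their 1043 entries, 1029 matched a gene of the table, directly or through the RefSeq gene table of GRCm38.p6, which was used only for names and for which genes are neighbours. Of the table's identifiers, 99.7% were found there. The 41 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Members passing the test were also counted with p-values adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with tables read by pandas 2.3.3.

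The genes named were fixed by a rule. Stab1 and Stab2 come first. Next come up to 12 genes per direction with the largest change among called genes whose knockout values all lie on 1 side of the wild-type values and whose mean in the higher group is at least 1 CPM, leaving out predicted or unnamed genes. In each called list up to 4 members with the smallest p are named, and in lists that were not called up to 2. Values of some genes the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

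The analysis was tested on simulated counts drawn from the means and sizes of these libraries. Each gene was drawn independently of the others, so the simulation lacks differences between libraries that many genes share. With 5 libraries against 3, the test called 40 of 98 genes changed 2-fold, 94 of 100 genes changed 4-fold and 9 of 12007 unchanged genes, over 12205 tested genes. With 4 against 3, it called 53 of 100, 99 of 100 and 5 of 11948, over 12148 tested genes. With no change simulated and independent genes, camera called 0 of 41 lists in the first design and 1 in the other.

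Alternatives fixed before the data were examined were leaving out each library, the replicate number as a block, no filter on low counts, DESeq2 size factors or upper-quartile scaling, the log2 Xist level as a covariate, the Wald test of DESeq2 1.42.0, limma-voom, a minimum absolute log2 fold change of 1, an adjusted p below 0.1, and the other list tests. Others were chosen after seeing the data: a clock index (log2 Arntl minus log2 Dbp) or an evenness-of-coverage measure as a covariate, each with and without knockout library 1, loess corrections (span 0.3) for gene length and GC content, and the minimum change and the DESeq2 test, each without knockout library 1. The evenness measure is the median coverage percent of genes of 5000 to 8000 bases with 100 to 150 reads. Gene length was known for 100% and GC content for 97.5% of tested genes.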

Results

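The series compared the liver transcriptome of 5-week-old Stab1 knockout mice with that of wild-type mice. Stab1 encodes stabilin-1, a scavenger receptor of sinusoidal endothelial cells and some macrophages. There were 5 knockout and 3 wild-type libraries of 4.85 to 10.8 M (mega) counted reads. Group values below are mean ± SD over 5 knockout and 3 wild-type libraries in CPM (reads scaled to library size), and adjusted p-values are from the edgeR quasi-likelihood test unless another test is named.

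Stab1 (gene identifier 192187) was nearly absent from every knockout library. Its level was 1.22 ± 0.378 CPM (SD, n = 5) in knockout and 51.0 ± 4.52 CPM (SD, n = 3) in wild-type liver, a log2 fold change of -5.38 (SE 0.22, edgeR adjusted p = 3.14e-06). Knockout libraries 1 to 5 held 7, 5, 16, 13 and 11 Stab1 reads, and wild-type libraries 1 to 3 held 594, 536 and 474. Reads covered 3.06% to 8.71% of the gene in knockout libraries and 73.1% to 90.6% in wild-type libraries. In an exact two-sided permutation test over the 56 divisions of the libraries, p = 0.0179, the smallest the design allows. Stab2, which encodes the homologous receptor stabilin-2, was not called. Its level was 55.7 ± 7.45 CPM in knockout and 65.6 ± 3.27 CPM in wild-type liver (log2 fold change -0.24, SE 0.14, adjusted p = 0.443).

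After Stab1, the smallest adjusted p-values belonged to Rpl26, Lrit1, Fam25c and Cwc22, and several called genes were near absence in 1 genotype. Rpl26 (identifier 19941), a ribosomal protein gene, fell from 31.1 ± 9.42 to 0.951 ± 0.189 CPM (log2 fold change -5.00, SE 0.24, adjusted p = 5.69e-06). Reads of Rpl26 can be shared with near-identical copies elsewhere in the genome, so its level is uncertain. Lrit1 (identifier 239037), which encodes a leucine-rich repeat membrane protein, fell from 16.8 ± 1.16 to 0.640 ± 0.214 CPM (log2 fold change -4.66, SE 0.23, adjusted p = 5.69e-06). Its neighbour Lrit2 (identifier 239038) had 122 reads in all wild-type and 2 in all knockout libraries, a ratio of 83.1 with an exact 95% counting interval of 22.5 to 693.7. The kinase subunit gene Camk2b had 197 reads against 6, a ratio of 44.7 (20.2 to 123.3), and Prom2, a prominin gene, had 144 against 3, a ratio of 65.4 (21.9 to 320.7).

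In the other direction, Ifi202b, an interferon-inducible gene of the p200 family, had 0 reads in all wild-type libraries and 350 reads in the knockout libraries. Its knockout level of 8.19 ± 4.39 CPM was at least 85.8-fold above a floor of 3 reads over the wild-type group. Its adjusted p was 0.0203, and its call was lost without knockout library 2 (0.0502), wild-type library 1 (0.0835) or wild-type library 2 (0.0690). Reads of this gene can be shared with other members of its family.

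In all, 28 of 12338 tested genes passed an adjusted p of 0.05, 9 higher and 19 lower in knockout liver, and 1682 genes had an unadjusted p below 0.05. The rule named 5 genes that rose and 12 that fell. The other rises were Il3ra, the interleukin-3 receptor alpha chain, from 1.98 ± 0.547 to 7.07 ± 1.08 CPM (log2 fold change 1.83, SE 0.25), Nkiras1 (1.13, SE 0.19), Cblc, a ubiquitin ligase of the Cbl family (1.07, SE 0.13), and Lyplal1 (0.95, SE 0.15). The other falls were Fam25c, from 32.7 ± 7.78 to 2.48 ± 0.599 CPM (log2 fold change -3.70, SE 0.22, adjusted p = 2.35e-05), the splicing factor gene Cwc22, from 77.7 ± 11.3 to 13.9 ± 1.85 CPM (-2.48, SE 0.15, adjusted p = 2.63e-05), the glutamate receptor gene Grid1 (-4.42, SE 0.66), the female-biased cytochrome P450 gene Cyp3a41a (-3.53, SE 0.46), Ildr2 (-2.66, SE 0.42) and Eif3j2 (-2.32, SE 0.33). Cyp3a41a and Eif3j2 have near-identical copies, so their counts are uncertain.

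**Figure D1:**
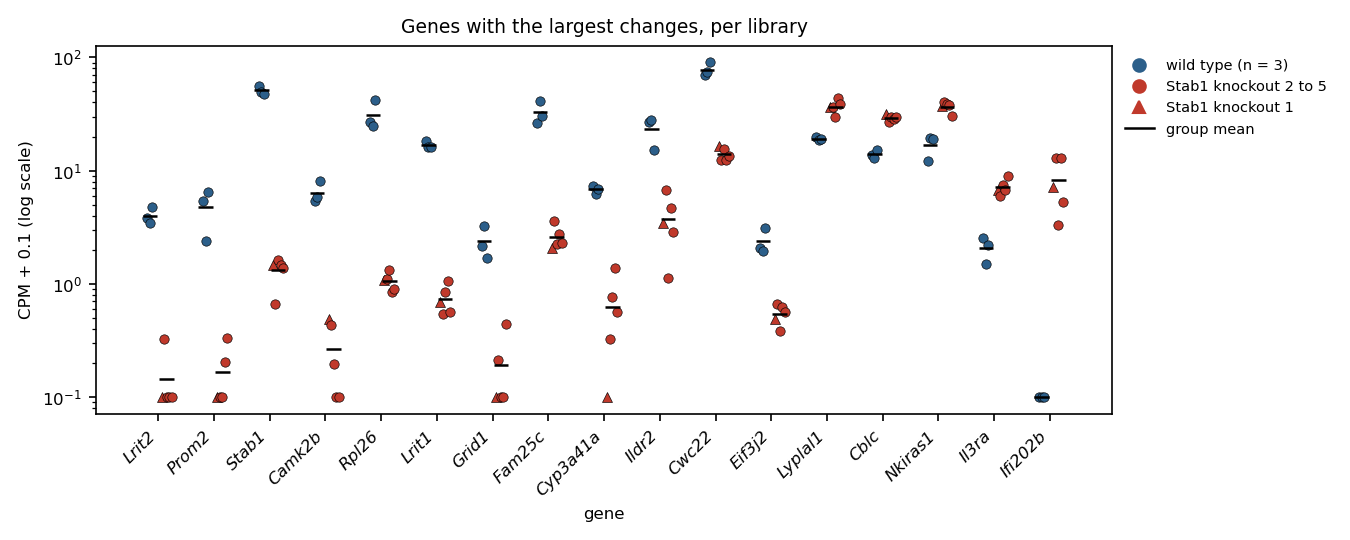
Level of each gene named by the rule in every library, as CPM plus 0.1 on a log scale. Blue points are wild-type libraries, red points knockout libraries, the triangle knockout library 1, and black bars group means; Stab1 lies at 1.22 CPM on average in knockout and 51.0 CPM in wild-type liver.

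Of 27 called genes other than Stab1 with a known place, 8 lay on the chromosome that carries Stab1, against 3.38% of tested genes (Fisher's exact two-sided p = 2.00e-06). All 8 lay within 100 tested genes of Stab1, a window that held 199 of the 416 other tested genes on that chromosome. They lay 28 to 99 tested genes away. They were Il3ra, Nkiras1, Fam25c, Grid1, Lrit1 and Lrit2, and the unnamed-type genes Gm3002 and 4930452B06Rik, chosen after their values were seen. Without knockout library 1, 19 of 113 such genes lay on that chromosome (Fisher's exact two-sided p = 7.45e-09), 14 of them within 100 tested genes of Stab1. The other 5, Cebpe, Ebpl, Adamdec1, Chmp7 and Gm9199, lay 109 to 243 tested genes away and were likewise chosen after their values were seen. With all libraries, among the other called genes, Ifi202b, Lyplal1 and Prom2 each lay within 50 tested genes of another called gene. The list of 25 genes immediately around the Stab1 locus, fixed beforehand, was not called (median log2 fold change 0.04, camera adjusted p = 0.839).

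The number of called genes rested on single libraries. Knockout library 1 was the shallowest and stood apart, with 3 Xist reads against 4445 to 8222 in every other library and 320 reads of the Y-linked gene Ddx3y against 0 to 4. It also held 278, 85 and 90 reads of the Y-linked genes Eif2s3y, Kdm5d and Uty, against 0 or 1 in the others. The labels give no sex, but by these reads knockout library 1 was male and the others female. The main fit thus mixed 1 male knockout library with female libraries. Without knockout library 1, 114 genes were called, 51 higher and 63 lower, including all 28. Without wild-type library 3, 93 genes were called, of which 25 were among the 28, and without wild-type library 1 or 2 the counts were 15 and 13. Stab1, Rpl26, Lrit1, Lrit2, Fam25c, Cwc22, Camk2b and Prom2 passed with any single library left out, and the other 9 named genes all lost their call without wild-type library 2, some of them also without other libraries. Their fitted log2 fold changes kept their sign in these fits, for example 1.62 to 2.02 for Il3ra, 1.01 to 1.14 for Cblc and -4.10 to -3.32 for Cyp3a41a. The DESeq2 Wald test called 137 genes, including all 28, and without knockout library 1, a combination chosen after seeing the data, it called 1083, 683 higher and 400 lower, again including all 28.

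Genes of cholesterol synthesis were lower in knockout liver. All 25 tested members had negative log2 fold changes, with a median of -0.58 (camera adjusted p = 6.94e-12; adjusted p = 0.65 with an estimated correlation). Over all genes 1 member was called, and 14 were called adjusted over the list alone. Among members that were not called, Mvd was at 24.0 ± 10.8 against 62.7 ± 22.1 CPM, and Stard4, a sterol carrier, had a log2 fold change of -0.72 (SE 0.15, adjusted p = 0.175). Without knockout library 1 the list median was -0.76, and 7 members fell over all genes and 18 over the list alone. The mean log2 CPM of the list was 7.83 and 8.07 in wild-type libraries 1 and 2. It was 7.20 in wild-type library 3, within the knockout range of 6.91 to 7.46. Knockout library 1 was the top of that range, and the next highest knockout library lay at 7.10. With the evenness of coverage as a covariate, chosen after seeing the data, the list median was -0.27 and no member was called over all genes.

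Fatty acid synthesis genes also had lower levels, with a median of -0.37 over 24 members (camera adjusted p = 0.00155; adjusted p = 0.65 with an estimated correlation). None of its members was called over all genes by edgeR, and 1 was called adjusted over the list alone. Fads2, a fatty acid desaturase, was at 184 ± 26.8 against 328 ± 26.5 CPM (log2 fold change -0.84, adjusted p = 0.102). The call of the list was lost without wild-type library 1 (adjusted p = 0.101) and with the coverage covariate (median -0.03, adjusted p = 0.418). With any single library left out the list median ran from -0.52 to -0.21. The list's mean log2 CPM was 7.94 and 7.73 in wild-type libraries 1 and 2 and 7.06 in wild-type library 3, within the knockout range of 6.82 to 7.66.

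Cell cycle genes were lower, with a median of -0.89 over 33 members, 31 of them negative (camera adjusted p = 4.25e-09; adjusted p = 0.65 with an estimated correlation), and 13 fell adjusted over the list alone but 0 over all genes. Cdc20 was at 2.24 ± 1.59 against 10.9 ± 7.54 CPM and Cdk1 at 2.67 ± 0.482 against 5.48 ± 2.25 CPM. The mean log2 CPM of this list was 2.81 and 2.71 in wild-type libraries 1 and 2 and 1.61 in wild-type library 3, below the knockout maximum of 2.03. With the coverage covariate the cell cycle median was -0.34 and the list stayed called (adjusted p = 0.00278), but with that covariate and without knockout library 1 the median was -0.04, with the camera direction turned to higher and no call (0.938). Periportal hepatocyte genes were lower with a median of -0.43 over 17 members (camera adjusted p = 0.00131; adjusted p = 0.65 with an estimated correlation), with Sds, serine dehydratase, at 79.5 ± 15.6 against 120 ± 7.68 CPM. Their mean log2 CPM was 8.81 and 8.59 in wild-type libraries 1 and 2 and 8.18 in wild-type library 3, within the knockout range of 8.04 to 8.31. With the coverage covariate the periportal median was -0.26 (adjusted p = 0.0423), and without knockout library 1 as well it was 0.09 (0.893). Pericentral genes were not called (median -0.01, camera adjusted p = 0.404).

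Ribosomal protein and respiratory chain genes were higher as lists. Ribosomal protein genes had a median of 0.30 over 36 members, 33 positive (camera adjusted p = 1.49e-05; adjusted p = 0.742 with an estimated correlation), and genes of the mitochondrial respiratory chain a median of 0.29 over 36 members, 31 positive (camera adjusted p = 3.17e-04; adjusted p = 0.742 with an estimated correlation). With all libraries, no member of either list was called by edgeR, also adjusted over the list alone. Without knockout library 1, 5 members of each list rose adjusted over the list alone and 0 over all genes. The ribosomal protein gene Rpl26, which was called lower, is not on the ribosomal protein list. Rps7 was at 466 ± 214 against 227 ± 65.6 CPM and Ndufs4 at 94.7 ± 17.4 against 62.2 ± 15.7 CPM. The ribosomal protein median was 0.19 without wild-type library 2 and 0.50 without wild-type library 3, and the list stayed called in both. With a correction for gene length the medians were -0.04 in both lists and neither was called (adjusted p = 0.985).

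Erythroid genes, neutrophil markers and adipose and mesothelial genes were called higher as lists. Erythroid genes had a median of 0.89, all 14 positive (camera adjusted p = 0.00132; adjusted p = 0.65 with an estimated correlation), with Car1 at 9.43 ± 1.49 against 4.90 ± 2.20 CPM, and the call was lost with the coverage covariate (adjusted p = 0.4). With all libraries, no erythroid member was called by edgeR over all genes or adjusted over the list alone. Without knockout library 1, 8 members rose adjusted over the list alone and 0 over all genes. The camera adjusted p was then 7.11e-05, or 0.778 with an estimated correlation. The erythroid mean log2 CPM was 3.89, 4.38 and 4.45 in knockout libraries 2, 4 and 5, above the wild-type range of 3.05 to 3.48, but 3.37 in knockout library 3 and 2.83 in knockout library 1, the latter below every wild-type library. Neutrophil markers had a median of 0.81 over 8 members (camera adjusted p = 0.0111; adjusted p = 0.65 with an estimated correlation), with Ltf at 1.17 ± 0.111 against 0.670 ± 0.105 CPM, and the call was lost without knockout library 1 (adjusted p = 0.192) or wild-type library 2 (0.0949) and with the length correction (0.0686). Ltf held only 6 to 12 reads in knockout and 6 to 8 in wild-type libraries (edgeR adjusted p = 0.338). Over all genes 0 neutrophil members were called, and 1 rose adjusted over the list alone. B and plasma cell markers were not called (6 members, median -0.33, adjusted p = 0.404). Adipose and mesothelial genes had a median of 1.01 over 5 members (camera adjusted p = 0.0339, or 0.65 with an estimated correlation), with Upk3b at 7.31 ± 4.34 against 2.22 ± 0.857 CPM. The call was lost without knockout library 4 (camera adjusted p = 0.0717) or wild-type library 3 (0.361), while the median ran from 0.76 to 1.38 with any single library left out. Hepatic stellate cell markers were lower, with a median of -0.21 over 18 members (camera adjusted p = 0.00774; adjusted p = 0.65 with an estimated correlation), and were not called without knockout library 1 (0.0917).

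The scavenger receptor list was called lower (17 members, median -0.01, camera adjusted p = 0.00881; adjusted p = 0.65 with an estimated correlation), but only through Stab1. Without Stab1 its other 16 members had a median of 0.00 and an adjusted p of 0.937. Female-biased liver genes were called lower (25 members, median -0.08, mean -0.53, camera adjusted p = 1.31e-04, or 0.742 with an estimated correlation). The list was not called without knockout library 1 (median 0.12, camera adjusted p = 0.238), in which its mean log2 CPM was -0.26 against at least 5.32 in every other library. Single members still differed without that library, where 14 of 25 were positive. Over all genes 4 members were called lower and 0 higher, and over the list alone 6 lower and 2 higher. Among the 4 was Cyp2c69 (log2 fold change -1.95, edgeR adjusted p = 0.00455). Fry's mixed test called the list in that fit (adjusted p = 1.96e-04). Male-biased genes were not called (median 0.82, adjusted p = 0.404), but without knockout library 1 they were called lower (median -0.85, adjusted p = 0.00683; adjusted p = 0.778 with an estimated correlation).

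No change was called in markers of sinusoidal endothelial cells, which express Stab1 (22 members, 6 of them positive, median -0.20, camera adjusted p = 0.120), with log2 fold changes of -0.76 (SE 0.22, adjusted p = 0.301) for Kdr, a vascular endothelial growth factor receptor, and 0.72 (SE 0.23, adjusted p = 0.327) for Maf. Nor was one called in Kupffer cell markers (26 members, 0.19, adjusted p = 0.124), monocyte markers (14 members, 0.26, adjusted p = 0.108), fibrosis and matrix genes (30 members, -0.15, adjusted p = 0.124), interferon-stimulated genes (41 members, 0.00, adjusted p = 0.814), acute phase genes (24 members, 0.35, adjusted p = 0.222) or bile acid genes (24 members, 0.08, adjusted p = 0.822). Single libraries and settings decided some of these. Sinusoidal endothelial markers were called lower without wild-type library 2 (adjusted p = 0.0357) and fibrosis genes lower without knockout library 4 (0.0218), while Kupffer cell markers were called higher without knockout library 2 (0.0216) or wild-type library 1 (0.0289) and monocyte markers higher without knockout library 3 (0.0441). Without knockout library 1 the Kupffer cell median was 0.10 (camera adjusted p = 0.760). With all libraries, monocyte markers were called higher with no filter on low counts (0.0154), and the coverage covariate called Kupffer cell markers higher (0.00769) and pericentral genes lower (0.0193). The acute phase median was -0.02 without knockout library 1 and 0.75 without wild-type library 3, with no call in either. A value past the threshold was reached by 12 of the 41 lists in all, 5 higher and 7 lower. With an estimated correlation camera called 0 lists, with 0 at an unadjusted p below 0.05, and fry called 0, with 5 at an unadjusted p below 0.05. Fry's mixed test, which takes changes in either direction, called 3 lists (scavenger receptors, immediate early genes and chemokines), and 21 without knockout library 1.

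**Figure D2:**
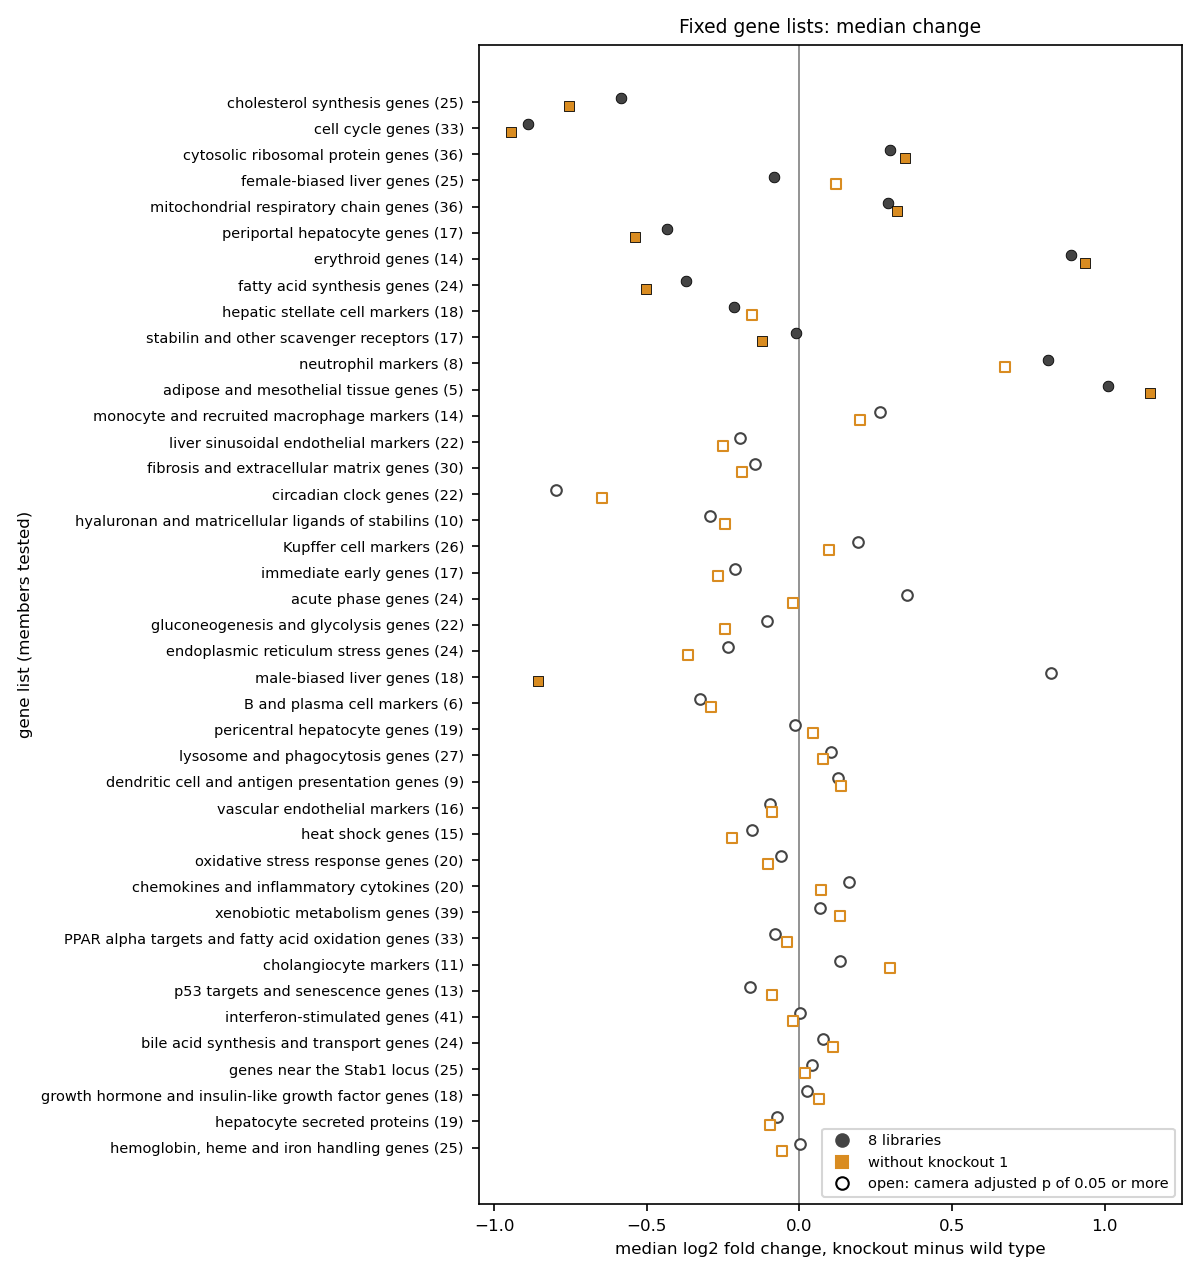
Median log2 fold change (knockout minus wild type) of each tested gene list, from all 8 libraries (circles) and without knockout library 1 (squares), with filled symbols for a camera adjusted p below 0.05. Cholesterol synthesis genes lie at -0.58 and -0.76.

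Libraries did not separate by genotype on the first principal component, which held 43.0% of the variance of log2 levels. Knockout library 1 and wild-type libraries 1 and 2 lay at 47.1, 30.9 and 33.1 on it, wild-type library 3 and knockout library 3 at -6.76 and -4.30, and knockout libraries 2, 4 and 5 between -40.7 and -26.8. The evenness of coverage divided them in the same way, at 56.9% to 59.0% in knockout library 1 and wild-type libraries 1 and 2 and at 49.7% to 52.7% in the others. On the second component, with 21.7% of the variance, wild-type libraries lay at 5.67 to 30.5 and knockout libraries at -47.7 to 3.51. Knockout library 1 was the lowest on it, and wild-type library 3 and knockout library 3 lay close together, at 5.67 and 3.51. Spearman correlations across genes between libraries ran from 0.930 to 0.990, the highest between wild-type libraries 1 and 2. Clock genes also differed within the wild-type group: Dbp was at 0.472 and 0.461 CPM in libraries 1 and 2 and at 145.5 CPM in library 3, against 7.82 to 65.2 CPM in knockout libraries.

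**Figure D3:**
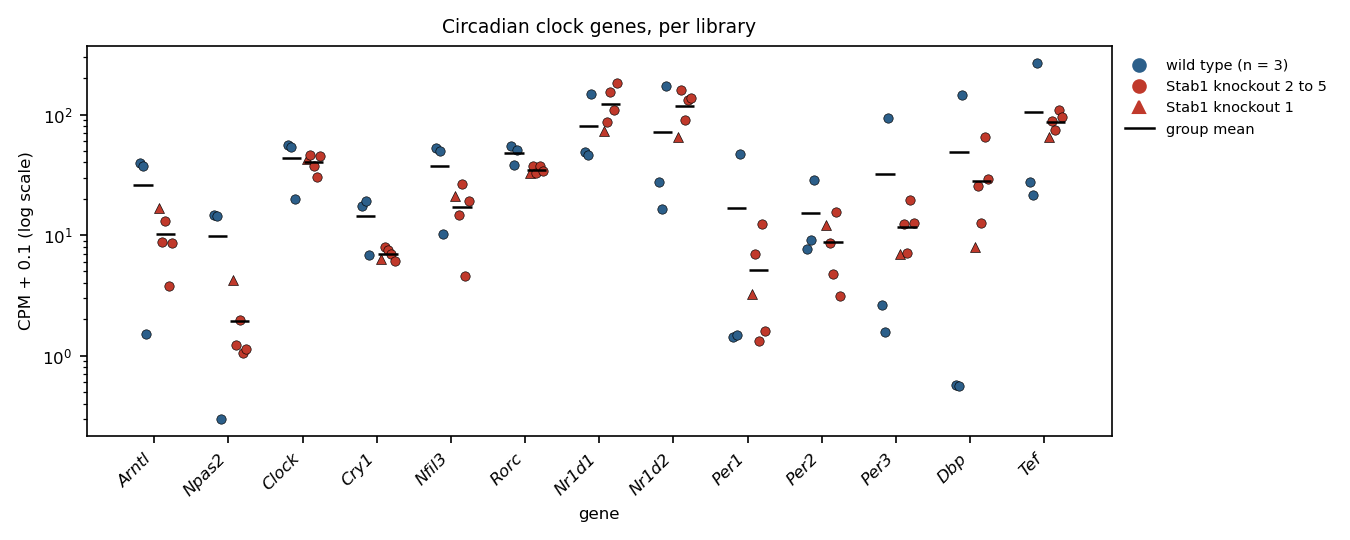
Level of circadian clock genes in every library, as CPM plus 0.1 on a log scale, with symbols as in the plot of named genes and black bars for group means. Wild-type library 3 lies opposite wild-type libraries 1 and 2 for Arntl and Dbp.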

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

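The tests of neighbouring genes, of knockout library 1, of respiratory chain genes under the length correction and of length-matched lists were chosen only after their results or closely related results had been seen, as were the coverage, clock, length and GC settings. A total of 84 items were examined for a knockout library far from the other 4, and 11 were found. Chance gives about 1 in 20 for independent, normally distributed values. The items include raw reads and CPM of related genes and lists, so the 11 cannot be set against that rate.

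Knockout library 1 lay apart in 7 of them. Its total of counted reads was the lowest, below the other 4 by most of the range (gap over range 0.725). It held 320 Ddx3y reads against 1 to 4 (0.991), Rn45s at 4250 CPM against 185 to 452 (0.934), the acute phase gene Saa1 at 2939 against 16.3 to 22.6 CPM (0.998) and the male-biased gene Mup20 at 3986 against 95.6 to 327 CPM (0.941). Its Mvd level was 42.8 against 16.2 to 23.1 CPM (0.740), and its mean log2 CPM of female-biased genes was -0.26 against 5.44 to 5.78 (0.945). Its levels of Ddx3y, Mup20 and female-biased genes go with a male animal and are not separate observations.

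Knockout library 2 lay apart for Stab1, at 0.557 against 1.27 to 1.51 CPM (0.749) and for Uroc1, at 282 against 370 to 388 CPM (0.831). It held 5 Stab1 reads against 7 to 16, so counting error may account for the Stab1 difference. For Lrit2 it held 2 reads (0.223 CPM) against 0 in the others, under the floor of 3 reads. The gap over range of 1 follows from the zeros there and does not set the library apart. Knockout library 5 lay apart for Hdc, at 18.7 against 3.57 to 7.73 CPM (0.725).

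The genes nearly absent from 1 genotype were weighed first. Called genes lay on the Stab1 chromosome 8.77 times as often as tested genes did, which is consistent with a chromosome segment inherited with the targeted locus, but 70.4% of them lay on other chromosomes, which such a segment does not explain. Without knockout library 1 the ratio was 4.94 and 83.2% lay on other chromosomes. On other chromosomes 7 of 19 called genes lay within 50 tested genes of another, against a median of 2 in 10000 random draws (permutation p = 0.0287). Without knockout library 1 it was 68 of 94 against 50 (permutation p = 5.00e-04). The draws do not allow for related genes that lie side by side. Calls near another without that library included Cyp2c29, Cyp2c38, Cyp2c68, Cyp2c40 and Cyp2c69, chosen after their values were seen. A different genetic background of the groups is a candidate explanation for calls on other chromosomes, which these draws cannot decide. The mice's strains are not given in the sources used here, and an effect of stabilin-1 itself on these genes stays open and untested.

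Cholesterol synthesis genes were weighed next. The list median of -0.58 was -0.35 with the clock index as a covariate (camera adjusted p = 3.10e-09), -0.76 without knockout library 1 and -0.57 with the length correction (camera adjusted p = 1.39e-12). Camera called the list in each, but very small camera p-values for it also came from divisions that mix the genotypes, so these calls decide nothing. The median hardly moved with the length correction, which argues against gene length as the whole source. Among knockout libraries, library 1 had the highest list mean log2 CPM (7.46 against 6.91 to 7.10). Leaving it out could thus only deepen the fall, which does not come from that library. With the clock index the median was smaller in size, so a linear clock trend may account for part of the fall. The clock index was 5.85 and 5.78 in wild-type libraries 1 and 2, -6.49 in wild-type library 3 and -4.06 to 1.08 in knockout libraries. The covariate removes only a linear trend on this index, so an effect of sampling time of another shape cannot be excluded. With the evenness of coverage as a covariate the median was -0.27, with the list still called (adjusted p = 7.96e-06), so a difference in library quality may account for part of it and the rest cannot be told apart from it with these libraries. An effect of the knockout stays open and untested beyond this, and the call itself is lost with an estimated correlation.

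Ribosomal protein and respiratory chain genes were weighed last. With the length correction their medians went from 0.30 to -0.0450 and from 0.29 to -0.0360, and neither list lay outside random lists of other genes of the same length (percentiles 25.5 and 53.1 of 10000 draws). With the GC correction the medians were 0.34 and 0.30, so GC content does not explain them. A difference between libraries in how well short transcripts were recovered may be the source. No shift of either list beyond that of other genes of its length was detected, and an effect of genotype on short transcripts as a whole stays open and untested.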

How the results depend on the processing

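Stab1 kept its direction and its call in every alternative run, with log2 fold changes of -5.48 to -5.19. Counts of called genes moved with single libraries. With 1 library left out they ran from 13 to 114, lists from 10 to 16 and the Stab1 log2 fold change from -5.48 to -5.19; the spread of single libraries within the groups is shown by these fits, and the cause was not tested. Replicate numbers do not pair the libraries (correlations of deviations between same-numbered libraries 0.12, -0.15 and -0.15), and with the replicate number as a block 14 genes were called, 13 of them among the 28, and 17 lists, 10 of them among the 12. With the block erythroid (median 0.21, adjusted p = 0.108) and adipose and mesothelial genes (0.79, 0.0586) were not called, and sinusoidal endothelial markers (0.0216) and fibrosis genes (0.00990), among others, were called lower. The Xist covariate gave 98 genes and the DESeq2 Wald test 137. That test without knockout library 1, chosen after seeing the data, gave 1083, and 29 genes taken by the naming rule that edgeR did not call with all libraries passed in it. Chosen after seeing the data, the clock covariate without knockout library 1 gave 125 genes, the coverage covariate without it 44 genes and 7 lists, 3 of them among the 12, and a minimum absolute log2 fold change of 1 without it 93 genes. Camera with an estimated correlation and fry called 0 lists, with 0 and 5 at an unadjusted p below 0.05, while fry's mixed test called 3. The cause of these differences was not tested. By the median alone, scavenger receptors turned positive without knockout library 2 (0.07) or 3 (0.03). Female-biased genes did so without knockout library 1 (0.12), and the camera direction stayed lower in each. Directions reversed for female-biased genes with the Xist covariate (median 0.29), for respiratory chain genes with the length correction (-0.0360), for ribosomal protein genes by the median alone with that correction (-0.0450) and, with the coverage covariate without knockout library 1, for periportal (0.0914), fatty acid synthesis (-0.0402, by the camera direction) and cell cycle genes (-0.0411, likewise), Acly (0.32) and Aldh1b1 (0.0247); the cause was not tested. Other scalings, limma-voom, no filter on low counts, an adjusted p below 0.1 and the GC correction gave 26 to 35 genes, and the length correction, the clock covariate and the coverage covariate with all libraries 22, 23 and 23. The coverage covariate with all libraries called 12 lists, 6 of them among the 12 called without it. Depth limits what can be seen of genes under 0.619 CPM in knockout library 1.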

Other observations

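The tests of divisions of the libraries were set before their results were seen, while the genes named from the fit without knockout library 1, the single clock genes and the coverage covariate were chosen after seeing the data.

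Without knockout library 1 the rule for named genes took others, each called in that fit. Ccr3, the eotaxin receptor, had a log2 fold change of 2.93 (edgeR adjusted p = 0.0104), Serpina7, which encodes thyroxine-binding globulin, 2.34 (0.0243), Cyp2c38 1.80 (0.0243), Leap2, a liver-expressed peptide, 2.45 (0.0459) and Pcp4l1 2.09 (0.00953). The transporter gene Abcb1b had -3.61 (0.00351) and Sp110 -4.10 (0.0199). With knockout library 1 included their adjusted p-values were 0.0503, 0.249, 0.374, 0.327, 0.245, 0.0791 and 0.301. Cholesterol-related genes that passed without it were Mvd (-1.71) and Stard4 (-0.81), among others.

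Clock genes differed between libraries of the same genotype. Dbp, an output gene of the clock, was at 0.472 and 0.461 CPM in wild-type libraries 1 and 2 and at 145.5 CPM in wild-type library 3, and Arntl, a core activator, at 39.4 and 36.9 CPM in the first pair and below 3.71 CPM in the last. In knockout libraries Dbp ranged from 7.82 to 65.2 CPM and Arntl from 3.71 to 16.8 CPM. The clock list was not called (22 members, median -0.80, camera adjusted p = 0.124), and single wild-type libraries decided this. It was called lower without wild-type library 1 (-0.86, adjusted p = 0.0175) or wild-type library 2 (-0.87, 0.00236), and without wild-type library 3 its median was 0.36 (0.531). Clock genes move in opposite directions, as Arntl and Dbp did between wild-type libraries, so a list-wide direction has no clear meaning. The list's mean log2 CPM was 3.50 and 3.30 in wild-type libraries 1 and 2 and 4.91 in wild-type library 3. These values lay on both sides of the knockout range of 3.59 to 4.12. Sampling times are not given in the sources used here.

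Other divisions of the libraries into groups of 5 and 3 were fitted in the same way. As many genes as the 28 came from 3 of the 56 divisions, the real one included, so chance cannot be excluded. The highest other count was 2232, from setting knockout library 1 with wild-type libraries 1 and 2 against the rest, a division that follows the evenness of coverage and points to a structure of the samples. With evenness of coverage as a covariate 23 genes were called. Without knockout library 1, 3 of 35 divisions gave as many as 114 genes, with 1044 the highest other, so chance cannot be excluded there either. For lists, 29 of 56 divisions gave as many as 12 (highest other 21), and 17 of 35 as many as 10 (highest other 22), so a count of called lists does not set genotype apart from other divisions. Counted for each called list, a camera p as small came from 1 of the 56 divisions for scavenger receptors, which rest on Stab1, 2 for cholesterol synthesis, 7 for ribosomal protein, 8 for respiratory chain, 9 for cell cycle and 10 for periportal genes. The count was 11 for stellate cell markers, 12 for neutrophil markers, 14 for fatty acid synthesis, 15 for adipose and mesothelial, 16 for erythroid and 35 for female-biased genes. Without knockout library 1 it was 1 of the 35 for scavenger receptors and for cholesterol synthesis, and 5 to 21 for the other lists. The low count for cholesterol synthesis does not set genotype apart. With all libraries, wild-type libraries 1 and 2 with any single knockout library against the rest gave a camera p of 8.11e-14 to 4.72e-11. The real division gave 1.69e-13. The pattern thus sets wild-type libraries 1 and 2 apart from the others.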
